A study of Mus musculus with 15 samples.

How the data were processed

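Total RNA from 15 samples of mouse brain tumour (3 placebo, 4 anti-PD1, 4 vorinostat and 4 combination) was sequenced from libraries made with an unstranded kit. Per the submitters' processing notes, FastQC, HISAT2, StringTie and DESeq2 were used with genome build mm10, and no versions are given. Whole reads recovered per library came to between 81.2 M and 161.5 M. The values are TPM as deposited by the authors, 1 table of 38172 gene symbols by 15 libraries, and what "adj" in the name of that table means is not given in the sources used here. All 15 columns matched a label by group and replicate number.

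The units were checked from the values. Within a library the TPM of 38167 of 38172 symbols (99.987%) came out as whole reads times a common factor, within 1e-06 reads. The symbols not recovered were Gm10925, Gm28661, Gm28437, Eef1a1 and Scd2, which hold between 10.8% and 24.0% of the TPM of a library, and they have no value in tests on reads. Of 28873 genes with reads in at least 5 libraries and 1 annotated gene of that symbol, 99.1% had an implied length within 1% of the gene span, introns included. For 20354 genes with several exons 99.1% lay within 1% of the span and 0.1% within 1% of the exon length. Genes with long introns therefore have lower TPM here than with exon lengths, and on log2(TPM + 1) with a 1 TPM filter this shrinks their changes or leaves them out. TPM sums lay between 996108 and 997722. The 10 symbols most abundant on average held between 17.1% (vorinostat library 3) and 39.5% (anti-PD1 library 2) of the TPM of a library. Pseudogenes held between 31.9% and 47.2%. Between 17019 and 18064 symbols had at least 1 TPM. The table lists no genes of the X, Y or mitochondrial chromosomes, so Hdac6, Hdac8 and Foxp3 are not analysed here. Coordinates come from GENCODE vM21, in which 36477 symbols (95.6%) were found.

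All tests used log2(TPM + 1) of the 19390 genes with at least 1 TPM in at least 3 libraries (12713 protein-coding, 2695 pseudogenes, 3982 other or unmatched). Gene tests, and each adjusted p of a gene, come from limma (lmFit, contrasts.fit, eBayes with a trend) with 1 mean per group and all 15 libraries in 1 fit, and the Benjamini-Hochberg adjustment at 0.05. The labels do not say what the replicate numbers mean. In anti-PD1 and the combination, libraries of the same number deviate from their group means together (correlations of 0.20 to 0.64 in 4 pairs). The pairing thus comes from the data. It is not the best match throughout, as combination library 4 had 0.30 with anti-PD1 library 3 and 0.29 with library 4. In combination vs anti-PD1 the fit with the number as a block, over all 15 libraries, is printed where it changes a call. In the 5 other pairs of groups at least 1 correlation was under 0.1, so pairing is not shown throughout there. It is not excluded either. Libraries of number 3 had correlations of 0.30 to 0.55 in every pair of groups, while number 1 of anti-PD1 and vorinostat had -0.28. A moderated test with 3 or 4 libraries per group pools the spread over genes and groups. Averaged effects are the mean of the effect with and without the other agent, and the interaction is their difference. Gene lists were tested with limma's camera at its preset correlation of 0.01, and beside it with camera at an estimated correlation, with fry, and with exact permutation of the list means over the 35 splits of the libraries, where the smallest p is 0.0286. Camera at the preset treats genes of a list as nearly independent, and its p-values are small where members move together. List p-values were adjusted over the 28 lists within a comparison. Of 30 lists fixed, regulatory T cell genes and mitochondrially encoded genes had fewer than 3 members measured and were not tested. Members under the filter of 1 TPM in 3 libraries are not counted in a list. Most listed T cell markers and cytotoxic lymphocyte genes lay below it, so both lists rest on the few that passed. Gzmb and Cd8a pass this filter only by their level with anti-PD1, alone or in the combination. The filter so favours positive anti-PD1 changes in the T cell and cytotoxic lists. The B and plasma cell list has the same bias. Mzb1 averaged 0.16 TPM in controls and 0.566 with vorinostat, against 1.54 with anti-PD1 and 1.82 with the combination. Cd79b averaged 0.592 and 0.556, against 1.04 and 0.759.

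The comparisons, tests, gene lists, alternatives and the rule for naming genes were written before the data were examined. For the comparisons with control the rule names the 10 largest changes in each direction with an adjusted p under 0.05, a mean of at least 5 TPM and no overlap between the groups, and for the others 5 in each direction. Where none pass it names the 3 of smallest p in each direction, as values that did not pass. Of each list described it names 2 to 4 members of smallest p, and 14 genes were fixed by name: Cdkn1a, H1f0, Hdac1, Hdac2, Hdac3, Pdcd1, Cd274, Cd8a, Gzmb, Ifng, H2-K1, Mki67, Olig2 and Pdgfra. Unnamed gene models and pseudogenes are left out by the rule. Genes named outside it are marked as chosen after their values were seen. The value of 1 list member is not reported here.

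Alternatives tried were other pseudocounts, no filter or a stricter one, median-of-ratios scaling, quantile normalization, the most abundant genes left out, eBayes without the trend or robust, arrayWeights, the replicate number as a block, the neuron mean as a covariate, other thresholds, only the groups compared, and leaving out each library. Added after the data were seen were voom on the recovered reads, protein-coding genes alone, and anti-PD1 library 2 and combination library 2 left out together.

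In simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale, the test found 65 and 94 in anti-PD1 vs control (15 false calls), 67 and 96 in combination vs control (6), 68 and 96 in vorinostat vs control (13) and 72 and 96 in combination vs vorinostat (6). It called 0 genes where nothing was changed. A list of 16 genes shifted by 0.8 was called and 0 others were. The simulated genes varied independently, so these counts do not test false calls of genes or lists where genes move together, as they do here. In other splits of the libraries of vorinostat vs control, camera called up to 17 lists. Reads were recovered for 4995 of 4995 simulated genes. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.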

Results

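RNA was sequenced from 15 samples of brain tumour taken from mice with an IDH-mutant low-grade glioma model. The tumours were started by injecting chicken DF-1 cells that carry viruses for mutant IDH and for the growth factor PDGFB into the brains of nestin-TVA mice, whose nestin-expressing cells can take up those viruses. Tumours were imaged by MRI on day 28, treatment ran for 9 days, and the tumours were collected on day 37 and cut into small pieces. The groups were placebo control (n = 3), anti-PD1, an antibody that blocks the T cell inhibitory receptor PD-1 (n = 4), vorinostat, an inhibitor of histone deacetylases (n = 4), and the combination of both (n = 4). Vorinostat was given at 1 mg per daily injection of 100 µl and anti-PD1 at 1 mg per injection. Each sample has 1 library. Whole reads recovered from the TPM values came to between 81.2 M (combination library 2) and 161.5 M (control library 3). Of the 38172 gene symbols listed, 19390 had at least 1 TPM in at least 3 of the 15 libraries and were tested. Changes are differences of mean log2(TPM + 1), given with their SE, and this scale understates the change of low genes. The labels do not say that the replicates are separate animals, so the p-values measure only the spread between samples. Coordinates are those of build mm10. The first principal component held 44.4% of the variance, and across libraries it had a correlation of 0.95 with the mean of 16 neuron genes and -0.95 with that of 27 cell cycle genes. The means of these 2 lists therefore stand beside each comparison. Of the genes fixed in advance, the T cell cytokine gene Ifng lay below the filter (mean 0.0597 TPM, highest 0.35).

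What vorinostat alone did was addressed by vorinostat vs control. MHC class I, T cell and cytotoxic genes stood at nearly the same level in both groups. The 16 measured MHC class I presentation genes, which carry peptides to the cell surface for CD8 T cells, had a mean change of 0. The 6 T cell markers and 5 cytotoxic lymphocyte genes that passed the filter, a minority of those listed, were at 0.10 and 0.07. No member passed in limma's test. The T cell gene Cd8a was at 0.0846 ± 0.147 TPM in controls (mean ± SD, n = 3) and 0.254 ± 0.193 with vorinostat (n = 4), the killer-cell protease gene Gzmb at 0.0203 ± 0.0351 and 0.029 ± 0.0581, and the MHC class I gene H2-K1 at 57.6 ± 21.8 and 61.7 ± 15.6. Genes known to respond to histone deacetylase inhibitors did not move as a group. Of 16 members 0 rose and 0 fell, the mean change was 0.02, the median -0.02 and camera's adjusted p 0.375. Among them the cell cycle inhibitor Cdkn1a had a change of -0.23 (SE 0.54), the linker histone gene H1f0 -0.27 (SE 0.24), the extracellular chaperone gene Clu 0.26 (SE 0.21) and the histone gene H2bc4 0.60 (SE 0.19). The deacetylase genes Hdac1, Hdac2 and Hdac3, which encode targets of the drug, had changes of -0.20, -0.16 and -0.11, each with an adjusted p of 1. The proliferation gene Mki67 had a change of -0.33 (SE 0.66), and the glioma lineage genes Olig2 and Pdgfra had 0.09 and -0.04. The cell cycle mean was -0.24 (adjusted p = 0.284).

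In vorinostat vs control 1 of 19390 genes changed, in limma's test. It is Gm38061, a gene model of unknown function on chromosome 11 (31698648 to 31699012), which fell by 2.65 (SE 0.12, adjusted p = 1.7e-07) from 5.59 ± 0.131 TPM in controls to 0.0507 ± 0.101. It was named after its values were seen, and it was also near 0 with anti-PD1 (0.0583 ± 0.117) and at 0 with the combination. It reached 1 TPM in the 3 controls alone, so leaving out any control library takes it below the filter. Without control library 1 or 2 there were 0 calls, without control library 3 there was 1 other gene, which rose, and without vorinostat library 3 there were 2. At an unadjusted p under 0.05 there were 488 genes, where chance gives 970, and voom on the recovered reads called 1. The genes of smallest p that did not pass were the small RNA gene Rn7s6 (1.23, SE 0.25), Mir5620 (0.63, SE 0.14) and the histone gene H2bc11 (0.70, SE 0.17, from 7.77 ± 1.66 to 13.2 ± 1.98 TPM). On the lower side they were Inka1, an inhibitor of a PAK kinase (-0.64, SE 0.17), Fibin (-1.10, SE 0.29) and Snord32a (-1.08, SE 0.30). Mir5620 and Snord32a lie inside Clcn4 and Rpl13a, from whose reads an unstranded kit cannot separate them. By limma's camera 4 of 28 lists were higher. They were 7 neutrophil genes (mean change 0.98, adjusted p = 0.0163), 16 neuron genes (0.17, adjusted p = 0.0205), 8 ependyma and choroid plexus genes (0.60, adjusted p = 0.000706) and 4 erythrocyte genes (1.11, adjusted p = 0.0205). With an estimated correlation each of these had adjusted p = 0.897, and fry called 0 lists (0 at an unadjusted p under 0.05). Without vorinostat library 4, which has the highest erythrocyte mean of its group, the neutrophil mean was 0.51, the neuron mean -0.08, the ependyma mean 0.35 and the erythrocyte mean 0.59. In that fit 0 lists passed. The neuron call also ended without control library 3 (0.04) or vorinostat library 1 (0.03), and the erythrocyte call without control library 2 (0.04). Without control library 1 the neuron mean was 0.33 and the erythrocyte mean 1.81, and without vorinostat library 3 the neuron mean was 0.53 and the ependyma mean 0.93.

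What the checkpoint antibody alone did was addressed by anti-PD1 vs control. By limma's camera, genes of antigen presentation, cytotoxic lymphocytes and plasma cells were higher with anti-PD1, genes of neurons were higher too, and genes of the cell cycle were lower. With an estimated correlation none of these lists passed (adjusted p = 0.496 to 0.592). Of the MHC class I presentation list 4 of 16 members rose, 0 fell and 12 did not pass (10 rose adjusted over the list alone), with a mean change of 0.88. The non-classical class I genes H2-Q7 (chromosome 17, 35439155 to 35443773) and H2-Q6 (chromosome 17, 35424850 to 35430055) rose by 2.02 (SE 0.47, adjusted p = 0.0376, from 2.48 ± 1.05 to 14.8 ± 9.34 TPM) and 1.85 (SE 0.43, adjusted p = 0.0367). These are near-identical copies, so how reads were split between them is uncertain. The classical gene H2-D1 rose by 1.37 (SE 0.34, adjusted p = 0.0441, from 298 ± 90.8 to 807 ± 330 TPM) and H2-T23 by 1.11 (SE 0.28, adjusted p = 0.045), while H2-K1 had a change of 1.37 that did not pass (SE 0.40, adjusted p = 0.0558). Gzmb (chromosome 14, 56258838 to 56262260) rose by 1.00 (SE 0.22, adjusted p = 0.0326), from 0.0203 ± 0.0351 TPM to 1.08 ± 0.478, and all 4 anti-PD1 libraries lay above all 3 controls. It was the 1 of 5 cytotoxic lymphocyte genes that passed (1 adjusted over the list alone, mean 0.61). As Gzmb, and Cd8a among T cell markers, enter only by their level with anti-PD1, the filter favours positive means of both lists. The helper T cell gene Cd4 rose by 1.64 (SE 0.42, adjusted p = 0.0459, from 0.855 ± 0.17 to 5.18 ± 2.64 TPM), 1 of 6 T cell markers (2 adjusted over the list alone; mean 0.69), and Cd8a had a change of 1.05 (SE 0.32, adjusted p = 0.0602). Of the MHC class II presentation list 0 of 9 passed (5 rose adjusted over the list alone; mean 0.98, median 0.51), with 2.25 for the invariant chain gene Cd74 (SE 0.67, adjusted p = 0.0579) and 2.08 for H2-Ab1. The interferon-inducible gene Gbp2 rose by 1.04 (adjusted p = 0.0486), 1 of 24 interferon response genes. The B cell attractant Cxcl13 rose by 0.90 (adjusted p = 0.0377), 1 of 14 chemokines. Adjusted over the list alone 2 chemokines rose and 1 fell, Ccl3 (-1.71), and 0 interferon response genes rose. The antibody light chain gene Igkc had a change of 2.97 (SE 1.07) and Mzb1, a plasma cell secretion factor, 1.06. Of 5 B and plasma cell genes 0 passed, and the filter favours a positive mean of this list too. Pdcd1, which encodes the receptor that the antibody binds, had a change of -0.50 (SE 0.20, adjusted p = 0.111), and Cd274, which encodes its ligand, 0.63 (SE 0.26, adjusted p = 0.116). The deacetylase genes Hdac1, Hdac2 and Hdac3 had changes of -0.81, -0.68 and -0.24, Olig2 -0.80, Pdgfra -0.72 and Cdkn1a -0.09 (0.09 with median-of-ratios scaling), and none passed. Of the genes that respond to deacetylase inhibitors 0 rose, 1 fell (H1f0) and 15 did not pass, with a mean of -0.03.

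The largest rises under the naming rule were in genes of antibody light and heavy chains and of striatal neurons. Igkj5 rose by 5.00 (SE 1.23), Ighv8-5 by 4.15 (SE 0.94; listed at 0 in the controls), Igkv14-111 by 3.53 (SE 0.77) and Igkv8-30 by 2.74 (SE 0.71). These segments are short and alike, so their single values are uncertain. Penk (chromosome 4, 4133531 to 4138819), which encodes an opioid peptide precursor, rose by 3.02 (SE 0.40, adjusted p = 0.0104) from 70.9 ± 25.7 TPM to 575 ± 149. The dopamine-signalling phosphatase regulator Ppp1r1b (chromosome 11, 98348404 to 98357796) rose by 2.59 (SE 0.49, adjusted p = 0.0239) from 68.7 ± 20.3 to 430 ± 156, the neuropeptide genes Nts and Tac1 by 2.79 and 2.59, and Lrrc10b and Slc35d3 by 2.61 and 2.56. Of the neuron list 3 of 16 rose, 0 fell and 13 did not pass (4 rose adjusted over the list alone), with a mean of 0.98. Those that rose were the GABA synthesis genes Gad1 by 1.46 (adjusted p = 0.0267) and Gad2 by 1.79 (adjusted p = 0.0493), and the glutamate receptor gene Grin1 by 0.99 (adjusted p = 0.0479). Among the largest falls were the matrix phosphoprotein gene Spp1 (chromosome 5, 104435118 to 104441050), which fell by 2.20 (SE 0.47, adjusted p = 0.0326) from 188 ± 79.2 to 42.7 ± 25.6 TPM. The fibroblast matrix genes Lum and Col3a1 fell by 1.97 (SE 0.34, adjusted p = 0.0206) and 1.54 (SE 0.40). Dcn fell by 1.09, so that 3 of 12 pericyte and fibroblast genes fell and 9 did not pass (5 fell adjusted over the list alone; mean -0.64). The mitotic genes Nek2 and Psrc1 fell by 1.58 (SE 0.40) and 1.52 (SE 0.34), and the histone gene H3c14 by 2.27 (SE 0.57). Further falls were Ankrd34c by 2.06, Snord32a by 1.47, Gpr161 by 1.44, Fibin by 1.29 and H1f0 by 0.90 (adjusted p = 0.0479, and -0.71 with adjusted p = 0.0516 after median-of-ratios scaling). Of the cell cycle list 1 of 27 fell, the cyclin gene Ccne1 by 0.41 (adjusted p = 0.0486), while 24 fell adjusted over the list alone. The mean was -1.34, with -1.64 for Mki67 (SE 0.66, adjusted p = 0.107) and -0.93 for the replication clamp gene Pcna.

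In anti-PD1 vs control 1026 of 19390 genes changed in limma's test, 344 higher and 682 lower (551 protein-coding genes and 292 pseudogenes), and 6638 had an unadjusted p under 0.05. The median change of all genes was -0.14 and moved to 0.01 with median-of-ratios scaling, under which 841 genes changed, 522 higher and 319 lower. The share that was higher went from 33.5% to 62.1%, and it was 65.3% with voom (394 higher, 209 lower). That scaling moved the median of combination vs anti-PD1 from 0.13 to 0 and that of the interaction from 0.18 to -0.01. Without control library 1, 2 or 3 the count was 0, 2 or 11, without anti-PD1 library 1, 2, 3 or 4 it was 155, 72, 4982 or 86. Without vorinostat library 1, 2 or 3 it was 596, 316 or 1940, and without combination library 1, 2, 3 or 4 it was 339, 1872, 595 or 636. None of the genes named here passed without control library 1. With the mean of the neuron genes as a covariate 22 genes changed, of which 17 were among the 1026, and none of the named rises and falls except Fibin kept its call.

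Camera called 12 of 28 lists in anti-PD1 vs control. Higher were MHC class I (adjusted p = 2.34e-07), MHC class II (0.000155), T cells (0.00352), cytotoxic lymphocytes (0.00674), B and plasma cells (mean 1.34, 0.00366), interferon (mean 0.30, 0.00118), chemokines (mean 0.30, 0.00492), neurons (9.33e-08), endothelium (mean 0.25, 0.0219), hypoxia (mean 0.26, 0.00612) and immediate early genes (mean 0.39, 0.0401), and the cell cycle was lower (1.77e-05). With an estimated correlation 0 lists passed, and 0 had an unadjusted p under 0.05. There the lists had adjusted p = 0.496 for MHC class I, T cells, cytotoxic lymphocytes, B cells, chemokines and neurons, 0.5 for MHC class II and hypoxia, 0.58 for endothelium, 0.592 for interferon and the cell cycle, and 0.616 for immediate early genes. Fry called 0 lists (smallest adjusted p = 0.092, 7 lists unadjusted). List calls ended without control library 1 for cytotoxic lymphocytes (0.45) and immediate early genes (0.22), without anti-PD1 library 4 for interferon (0.08) and immediate early genes (0.18). They also ended without anti-PD1 library 1 for endothelium (0.20), and without anti-PD1 library 3 (0.20), vorinostat library 3 (0.39) or combination library 2 (0.39) for immediate early genes. Means that moved by over 1.5 times were those of chemokines, at 0.18 without anti-PD1 library 4 and 0.46 without library 1, of interferon, at 0.16 without control library 1 and 0.51 without anti-PD1 library 1, of hypoxia, at 0.17 without anti-PD1 library 4, and of immediate early genes, at 0.66 without control library 2 and 0.82 without anti-PD1 library 2. With the neuron mean as a covariate the calls of T cells (0.38), B and plasma cells (0.85), hypoxia (0.15), endothelium (0.01) and the cell cycle (-0.29) ended, and with a mean of at least 5 TPM that of chemokines (0.10).

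**Figure D1:**
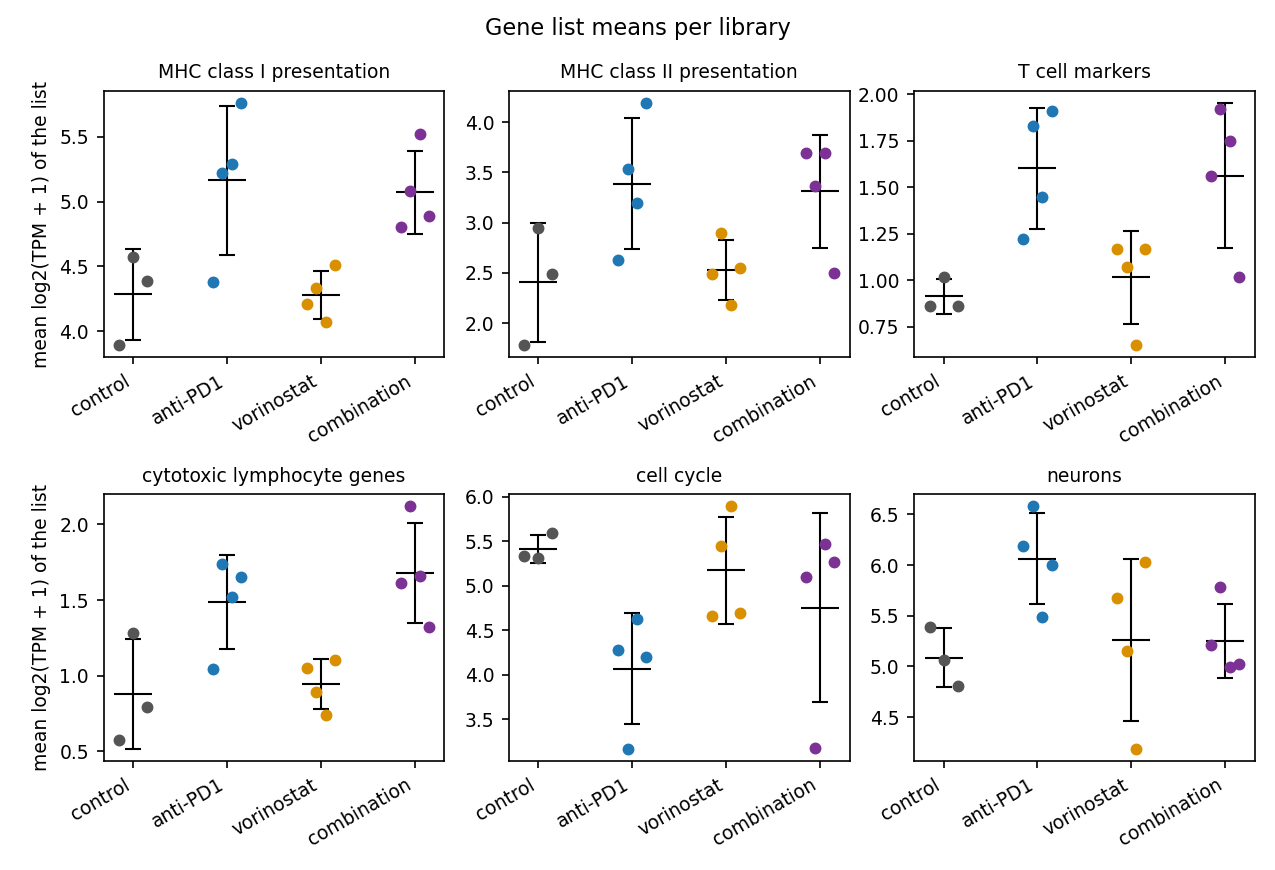
Mean log2(TPM + 1) of 6 gene lists in each library, by group; points are libraries, lines are group means and bars are SDs. The MHC class I mean is 4.28 ± 0.35 in controls, 5.16 ± 0.57 with anti-PD1, 4.28 ± 0.19 with vorinostat and 5.07 ± 0.32 with the combination, and the cell cycle mean is 5.41 ± 0.16, 4.07 ± 0.62, 5.17 ± 0.60 and 4.75 ± 1.06.

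What both agents together did was addressed by combination vs control. By camera at its preset, genes of MHC class I, cytotoxic lymphocytes, T cells and chemokines were higher, and with an estimated correlation 0 lists passed (smallest adjusted p = 0.0768). Lilr4b, an inhibitory receptor gene of myeloid cells on chromosome 10 (51480632 to 51486703), rose by 1.42 (SE 0.15, adjusted p = 0.00216) from 1.15 ± 0.402 TPM to 4.73 ± 0.686. It has a near-identical neighbour, so its value is uncertain. Prr7, which encodes a membrane adaptor found in synapses and T cells (chromosome 13, 55464267 to 55473154), rose by 1.23 (SE 0.14, adjusted p = 0.00343) from 2.29 ± 0.481 to 6.75 ± 1.13. The skin protease gene Klk7 (chromosome 7, 43811294 to 43816359) rose by 1.13 (SE 0.15, adjusted p = 0.0116), from a listed 0 in all 3 controls to 1.22 ± 0.355. Gm38061 fell by 2.72 (SE 0.12, adjusted p = 1.23e-07). These 4 genes were named after their values were seen, and they were the only ones of 19390 that changed (3 higher, 1 lower). At an unadjusted p under 0.05 there were 1117. With only these groups in the fit Gm38061 alone passed. Klk7 lost its call without any control library (adjusted p = 0.0594, 0.0979 and 0.0902), and without combination library 1, 2 or 3 it lies below the filter. The count was 2, 2 and 3 without control library 1, 2 and 3, and 13 without combination library 4.

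Gzmb, Cd8a, H2-K1 and Cd274 stood higher with the combination than in controls without passing. Gzmb was at 1.20 ± 0.584 TPM (change 1.07, SE 0.22, adjusted p = 0.16), Cd8a at 1.72 ± 1.27 (1.20, SE 0.32, adjusted p = 0.369), H2-K1 at 140 ± 51.8 (1.28, SE 0.40) and Cd274 at 2.99 ± 0.635 (0.69, SE 0.26). Of the MHC class I list 0 of 16 passed (6 rose adjusted over the list alone; mean 0.79), with 1.24 for H2-D1, 1.68 for H2-Q7 and 1.39 for H2-Q6. Of 5 cytotoxic lymphocyte genes 3 rose adjusted over the list alone (mean 0.80), with 1.41 for the granule gene Nkg7 and 1.01 for the T cell chemokine Ccl5. Of 6 T cell markers 3 did (mean 0.65), with 0.38 for the kinase gene Lck. Of 14 chemokines 4 did (mean 0.62), with 1.88 for Cxcl9 and 1.09 for Cxcl11, both attractants of activated T cells. Of 9 MHC class II genes 4 did (mean 0.91), with 1.90 for Cd74. The monocyte and macrophage mean was 0.47, with 2.22 for the arginase gene Arg1 (SE 0.61). The interferon mean was 0.39, with 1.18 for Gbp2 and 1.41 for the GTPase gene Iigp1, and the immediate early and heat shock mean was 0.76, with 1.42 for Junb and 2.51 for the chaperone gene Hspa1b (SE 1.01). The genes of smallest p that did not pass were the neuropeptide precursor Vgf (2.04, SE 0.33, adjusted p = 0.0935), Fam43b (0.70), Ccdc85b (0.96), Lum (-1.30), the ATP synthase subunit gene Atp5k (-0.33) and Fibin (-1.07). Cdkn1a had a change of 0.20, H1f0 -0.27, Hdac1 -0.14, Hdac2 -0.12, Hdac3 -0.04, Pdcd1 -0.30, Mki67 -1.16, Olig2 -0.43 and Pdgfra -0.61.

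In combination vs control camera called 14 of 28 lists, each given here with its adjusted p and then the adjusted p with an estimated correlation. Higher were MHC class I (2.98e-12, 0.162), cytotoxic lymphocytes (3.32e-06, 0.0768), chemokines (3.08e-07, 0.0768), T cells (6.98e-06, 0.0935) and monocytes and macrophages (0.000233, 0.0935). So were MHC class II (1.75e-07, 0.202), interferon (1.12e-06, 0.418), hypoxia (mean 0.30, 0.000101, 0.202) and immediate early genes (1.57e-05, 0.343). B and plasma cells (mean 0.97, 0.00777, 0.343), neutrophils (mean 1.01, 0.013, 0.343) and endothelium (mean 0.19, 0.00777, 0.418) were higher too. Lower were pericytes and fibroblasts (mean -0.45, 0.000205, 0.153) and the cell cycle (mean -0.66, 3.74e-05, 0.651). Fry called 0 lists (smallest adjusted p = 0.0713, 6 unadjusted). The MHC class I mean lay higher than in controls at the smallest p that 35 exact splits can give, 0.0286. Neuron genes stood at 0.16 (adjusted p = 0.141). Without combination library 2, whose cell cycle mean is far below its group, the cell cycle mean was -0.13, the B and plasma cell mean 0.62 and the neutrophil mean 0.77, and these calls ended. Without control library 1 the B and plasma cell call ended (0.65), without control library 2 that of pericytes (-0.24) and without control library 3 that of endothelium (0.11). The immediate early mean was 0.40 without combination library 4, where that list is highest, and the B and plasma cell mean 1.46. Without control library 1 the MHC class II mean was 0.59 and the interferon mean 0.24, and without combination library 3 the latter was 0.25. With a mean of at least 5 TPM the monocyte call ended (0.24).

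**Figure D2:**
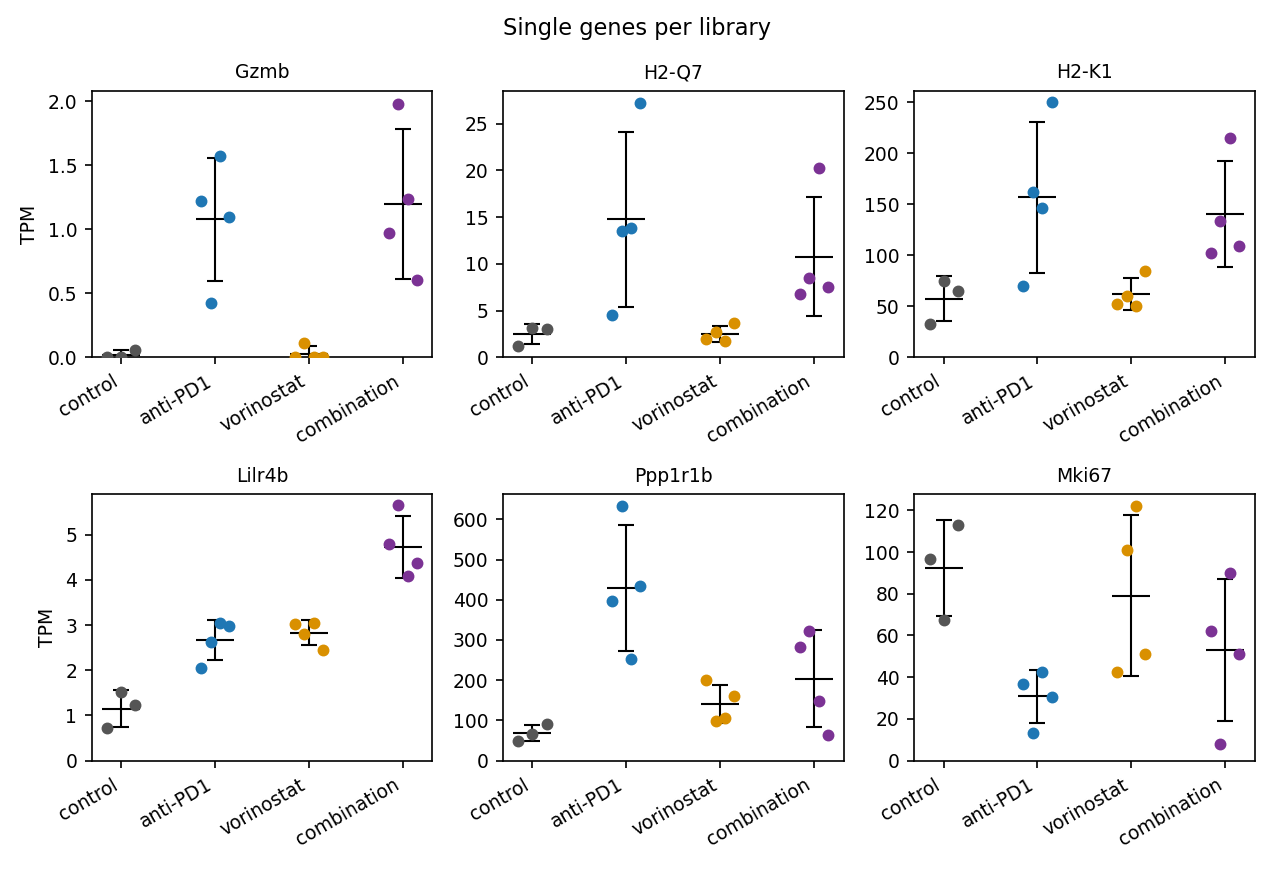
TPM of Gzmb, H2-Q7, H2-K1, Lilr4b, Ppp1r1b and Mki67 in each library, by group; points are libraries, lines are means and bars are SDs. Gzmb is at 1.08 ± 0.478 and 1.20 ± 0.584 TPM in the anti-PD1 groups and at 0.0203 ± 0.0351 and 0.029 ± 0.0581 in the others.

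What vorinostat added to anti-PD1 was addressed by combination vs anti-PD1. Gzmb, Cd8a and H2-K1 did not pass. Gzmb had a change of 0.08 (SE 0.20), Cd8a 0.15 (SE 0.29), and H2-K1 -0.09 (SE 0.37). The MHC class I list had a mean of -0.09, T cells -0.04 (median 0.13) and cytotoxic lymphocytes 0.19. Monocyte and macrophage genes (mean 0.31, adjusted p = 0.658), chemokines (0.31, adjusted p = 0.983) and dendritic cell genes (0.19, adjusted p = 0.983) stood higher with the combination in all 4 pairs of the same number without passing, and were at 0.18, 0.18 and 0.07 with median-of-ratios scaling. For monocytes all 4 combination libraries lay above all 4 others (exact p = 0.0286, 0.532 adjusted over the lists). Higher in all 4 pairs too were p53 targets, DNA methylation and IDH genes, driver genes of the model, glioma progenitors and the cell cycle. Neurons and astrocytes were lower in all 4, and the median change of all genes was 0.13. Of 19390 genes 3 rose and 0 fell in limma's test, and these were named after their values were seen. With the replicate number as a block, as library numbers go together in these 2 groups, 115 changed (88 higher, 27 lower). The block was fitted over all 15 libraries, so it also tied control and vorinostat libraries, for which pairing is not shown throughout. The 3 are Klk7 by 1.08 (SE 0.13, adjusted p = 0.0336), the non-coding gene Gm17300 by 0.77 (SE 0.11, adjusted p = 0.0378, from 16 ± 0.191 to 28.1 ± 2.08 TPM) and 2700046G09Rik, a non-coding gene beside Sgms1, by 0.76 (SE 0.10, adjusted p = 0.0378, from 4.43 ± 0.524 to 8.16 ± 0.707 TPM). Gm17300 overlaps Snhg3 and Rcc1, whose reads cannot be told from its own. At an unadjusted p under 0.05 there were 4558 genes, voom called 1, and median-of-ratios scaling 2 (1 higher, 1 lower). The count was 0 without control library 1 or 3, vorinostat library 2 or 4 or combination library 2 or 3. None of the 3 genes passed without anti-PD1 library 1 or 4 (1 other gene) or combination library 1 (3 others). None passed with a pseudocount of 0.1, quantile normalization, the neuron mean as a covariate or only these groups in the fit. The count was 671 without anti-PD1 library 3, 6 without vorinostat library 3 and 7 without combination library 4. Values that did not pass include the long non-coding RNA gene Neat1 (1.27, SE 0.20, adjusted p = 0.056), Pde6d (0.54), the calcium regulator Tmem203 (0.60, adjusted p = 0.0537), Rap1gap (-0.61, adjusted p = 0.0537), the hormone receptor gene Mchr1 (-1.15) and Plcxd1 (-1.12). With the block Neat1, Rap1gap and Plcxd1 (adjusted p = 0.03 each), Pde6d (0.0324) and Tmem203 (0.0428) passed. Among genes that respond to deacetylase inhibitors H1f2 had a change of 1.05 (SE 0.30), H2bc12 0.49 and H2bc4 0.43, and 0 of 16 passed (with the block H1f2, adjusted p = 0.0426, and H2bc12, 0.0475). Their mean of 0.13 turns to -0.03 with median-of-ratios scaling. Cdkn1a had a change of 0.29, H1f0 0.63, Hdac1 0.66, Hdac2 0.57, Hdac3 0.20, Pdcd1 0.20, Cd274 0.06 (-0.07 with median-of-ratios scaling), Mki67 0.47, Olig2 0.37 and Pdgfra 0.10 (-0.06 likewise). Camera called 2 of 28 lists. Neurons were lower (mean -0.82, 0 of 16 members past, adjusted p = 2.54e-09). The cell cycle was higher (mean 0.68, 0 of 27 members past and 1 adjusted over the list alone, adjusted p = 0.0409). With an estimated correlation both had adjusted p = 0.999, and fry called 0 (2 unadjusted). The cell cycle call ended without control library 1 (0.68), anti-PD1 library 2 (0.38) or 3 (0.87) or combination library 1 (0.57), 3 (0.44) or 4 (0.51), and its mean was -0.20 with the neuron mean as a covariate and 1.21 without combination library 2.

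What anti-PD1 added to vorinostat was addressed by combination vs vorinostat. By camera at its preset, MHC class I, cytotoxic lymphocyte, chemokine and T cell genes were higher, and with an estimated correlation 0 lists passed. B and plasma cell genes (mean 0.67, adjusted p = 0.0805) and neutrophil genes (0.03, adjusted p = 0.928) did not pass. The MHC class I mean rose by 0.79, with 1.65 for H2-Q7, 1.17 for H2-D1 and 1.18 for the immunoproteasome gene Psmb9 (10 of 16 adjusted over the list alone, 0 over all genes). The cytotoxic lymphocyte mean was 0.73, with 1.06 for Gzmb (SE 0.20, adjusted p = 0.22), 0.98 for Ccl5 and 1.43 for Nkg7 (3 of 5 adjusted over the list alone). The chemokine mean was 0.57, with 1.27 for Cxcl11 and 1.86 for Cxcl9 (4 of 14 adjusted over the list alone). The T cell mean was 0.55, with 1.00 for Cd8a (SE 0.29, adjusted p = 0.617, 1 of 6 adjusted over the list alone). The monocyte gene Ly6c2 had a change of 1.12 and Arg1 1.44, in a list with a mean of 0.32. Of 19390 genes 2 rose, and these were named after their values were seen. They are Tmem203 (chromosome 2, 25255439 to 25256292) by 0.69 (SE 0.09, adjusted p = 0.0443, from 37.4 ± 2.13 to 60.9 ± 5.54 TPM) and Klk7 by 1.13 (SE 0.13, adjusted p = 0.0194). There were 932 genes at an unadjusted p under 0.05, against 970 by chance, and voom called 1. The count was 0 without vorinostat library 1, 2 or 4 or combination library 2 or 3. It was 1 without any control library or anti-PD1 library 1 or 2 (Klk7 each time), 1 other gene without vorinostat library 3 or combination library 1, and 9 without combination library 4. With a pseudocount of 0.1, a mean of at least 5 TPM or only these groups in the fit it was 0. It was also 0 without anti-PD1 library 2 and combination library 2 together. With the replicate number as a block it was 0 too, though pairing of these 2 groups by number is not shown throughout. With median-of-ratios scaling, quantile normalization or voom Klk7 alone passed. Not past the threshold were Chp2 (-0.83, SE 0.22), the sulfur enzyme gene Tst (-0.67, SE 0.18) and Rn7s6 (-0.79, SE 0.24), and the fixed genes Cdkn1a (0.42), H1f0 (0), Hdac1 (0.06), Hdac2 (0.04), Hdac3 (0.06), Pdcd1 (-0.16), Cd274 (0.66), H2-K1 (1.13), Mki67 (-0.84), Olig2 (-0.52) and Pdgfra (-0.57).

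Camera called 17 of 28 lists in combination vs vorinostat, given in the same way. Higher were MHC class I (6.96e-14, 0.184), interferon (mean 0.43, 1e-07, 0.426), MHC class II (mean 0.78, 6.62e-07, 0.265), chemokines (3.39e-06, 0.121) and cytotoxic lymphocytes (2.11e-05, 0.121). T cells (7.61e-05, 0.184), hypoxia (mean 0.32, 7.61e-05, 0.265), immediate early genes (mean 0.65, 0.000886, 0.453), endothelium (mean 0.19, 0.00884, 0.426) and monocytes and macrophages (0.0222, 0.265) were higher too. Lower were the cell cycle (mean -0.42, 0.000343, 0.563) and oligodendrocyte progenitors and glioma (mean -0.34, 0.00208, 0.503). So were pericytes (mean -0.21, 0.00566, 0.265) and astrocytes (mean -0.16, 0.0118, 0.276), with -0.49 for the water channel gene Aqp4, and microglia (mean -0.09, 0.032, 0.426), with -0.42 for the purine receptor gene P2ry12. Ependyma (mean -0.40, 0.032, 0.503) and erythrocytes (mean -0.94, 0.032, 0.485) were also lower. Neurons had a mean of -0.02 (adjusted p = 0.571). Fry called 0 lists (smallest adjusted p = 0.0731, 7 unadjusted). The cyclin gene Ccne1 moved against its list, with a change of 0.42. Without combination library 2 the cell cycle mean was 0.11 and the progenitor mean 0.04, and these calls ended, as they did without vorinostat library 3 (-0.18 and -0.08). Without vorinostat library 4 the calls of microglia (-0.09), monocytes (0.29), astrocytes (-0.10), pericytes (-0.12), ependyma (-0.15) and erythrocytes (-0.41) ended. Those of microglia, ependyma and erythrocytes also ended without vorinostat library 1 (-0.09, -0.24 and -1.08), combination library 3 (-0.09, -0.26 and -0.96) or combination library 4 (-0.09, -0.17 and -0.96), and those of ependyma and erythrocytes without combination library 1 (-0.42 and -0.82). Calls ended further for monocytes without combination library 2 (0.28), for astrocytes and immediate early genes without combination library 4 (-0.10 and 0.29), and for endothelium without vorinostat library 2 (0.16) or 3 (0.12). Without vorinostat library 3 the astrocyte mean was -0.32 and the ependyma mean -0.73, without vorinostat library 2 the astrocyte mean was -0.10, without vorinostat library 4 the endothelial mean was 0.31, and without combination library 2 the ependyma mean was -0.76. With a mean of at least 5 TPM the calls of chemokines (0.29), monocytes (0.07), endothelium (0.13) and ependyma (-0.21) ended.

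**Figure D3:**
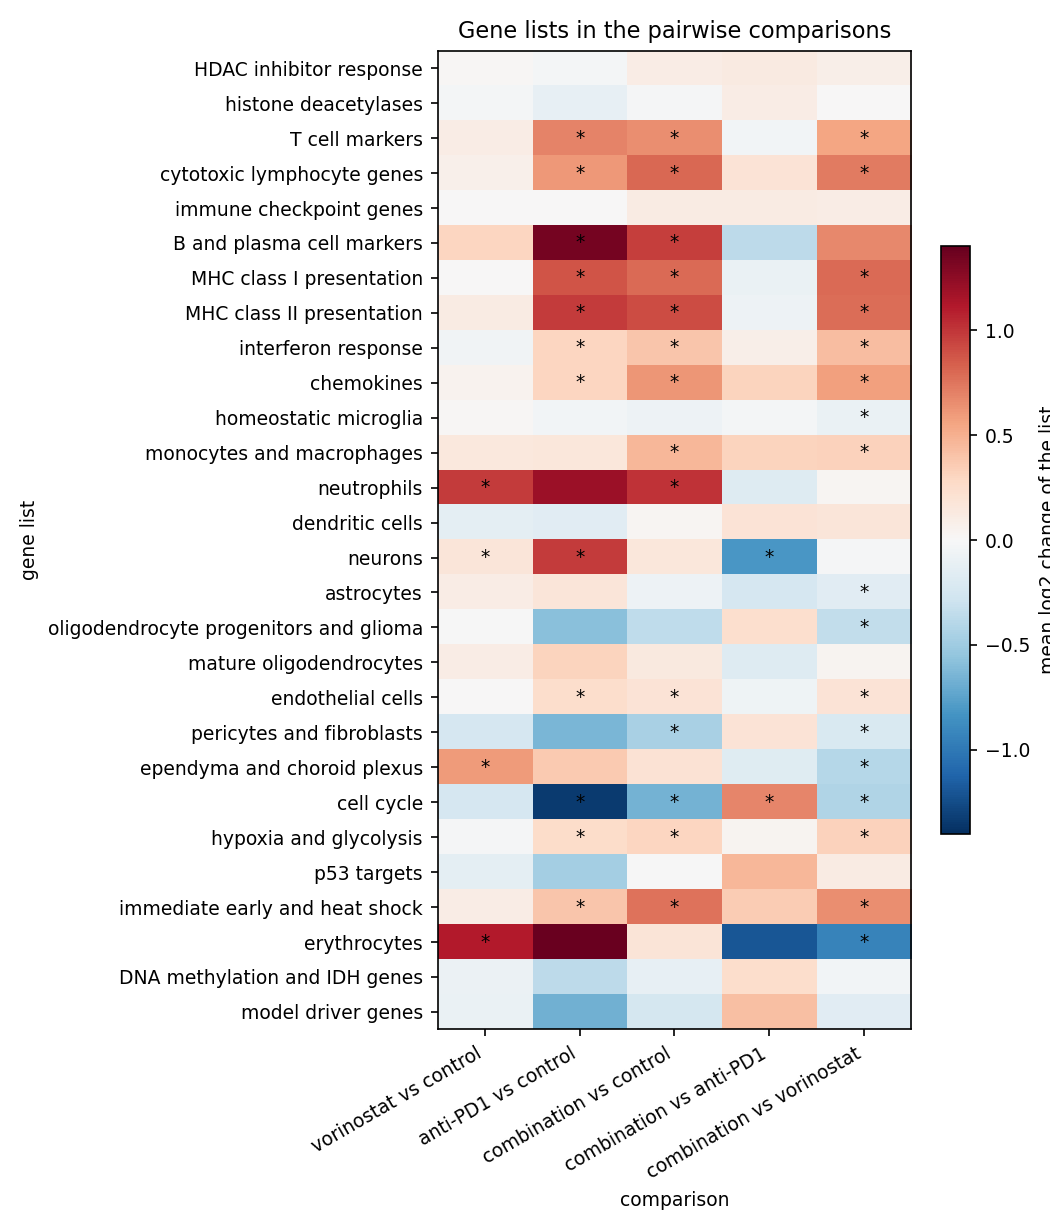
Mean log2 change of the 28 gene lists in each comparison, as colour; an asterisk marks an adjusted p under 0.05 with limma's camera at its preset correlation. The MHC class I list is at 0.88 in anti-PD1 vs control, 0.79 in combination vs control and combination vs vorinostat, and 0 in vorinostat vs control.

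Averaged over both backgrounds, anti-PD1 raised 3 of 16 MHC class I genes and 1 of 5 cytotoxic lymphocyte genes, while camera with an estimated correlation called 0 lists (smallest adjusted p = 0.195, 4 unadjusted). Gzmb rose by 1.03 (SE 0.15, adjusted p = 0.0161), H2-Q7 by 1.83 (SE 0.32, adjusted p = 0.0331), H2-Q6 by 1.59 (SE 0.29), H2-D1 by 1.27 (SE 0.23, adjusted p = 0.035) and Gbp2 by 1.06 (SE 0.19, adjusted p = 0.0331). The antibody segment gene Igkv6-17 rose by 3.03 (SE 0.55). Fam43b (chromosome 4, 138394092 to 138396528) rose by 0.64 (SE 0.08, adjusted p = 0.0088) and Ccdc85b, which overlaps Fosl1, by 0.78 (SE 0.11, adjusted p = 0.0161). Lum fell by 1.44 (SE 0.23, adjusted p = 0.0296). Cd8a (1.02, adjusted p = 0.0514), H2-K1 (1.25, adjusted p = 0.0535), Cxcl11 (0.91, adjusted p = 0.0514) and Iigp1 (1.57, adjusted p = 0.0514) did not pass. Neither did Cd274 (0.64, adjusted p = 0.0918), the respiration genes Ndufc2 and Atp5k (-0.34 and -0.26), Trim59 (-0.48), Cdkn1a (0.16), H1f0 (-0.45), Hdac1 (-0.37), Hdac2 (-0.32), Hdac3 (-0.09), Pdcd1 (-0.33), Mki67 (-1.24), Olig2 (-0.66) or Pdgfra (-0.65). By fry, which does not compare a list with other genes, 5 of 28 lists moved. T cells (mean 0.62), cytotoxic lymphocytes (0.67), MHC class I (0.83) and chemokines (0.44) were higher, each with adjusted p = 0.0182, and pericytes and fibroblasts (-0.42) lower with adjusted p = 0.0207. Of their members 0 of 6, 1 of 5, 3 of 16 and 0 of 14 rose over all genes, and 5, 3, 13 and 7 adjusted over the list alone. For T cells and cytotoxic lymphocytes the filter favours a rise, as Gzmb and Cd8a pass it only by their level with anti-PD1. Camera called 14 lists, 11 higher and 3 lower, among them MHC class I (5.67e-12), neurons (mean 0.48, 1.18e-05, adjusted p = 0.438 with an estimated correlation, and 0.30 without vorinostat library 3) and, lower, the cell cycle (mean -0.88, 6.44e-07, adjusted p = 0.499 with an estimated correlation).

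For anti-PD1 averaged over both backgrounds 91 genes changed in limma's test (46 higher, 45 lower), and 4276 had an unadjusted p under 0.05. The count was 49 with voom (39 higher, 10 lower) and 35 among protein-coding genes alone (31 higher, 4 lower). Fam43b passed without each library in turn, and Gzmb and Ccdc85b failed only without control library 1 (adjusted p = 0.0636 for each). H2-Q7, H2-Q6, H2-D1, Gbp2 and Igkv6-17 lost their calls without any control library, anti-PD1 library 2, vorinostat library 1, 2 or 3 or combination library 2, and with the neuron mean as a covariate. H2-Q6, H2-D1 and Gbp2 also lost them without anti-PD1 library 4 or combination library 3, and Igkv6-17 without combination library 1 or 3. Lum lost its call without any control library, anti-PD1 library 2 or vorinostat library 2 or 3. The number of genes that changed was 7, 15 and 12 without control library 1, 2 and 3, and 25, 565 and 40 without anti-PD1 library 2, 3 and 4. It was 50, 13, 19 and 335 without vorinostat library 1, 2, 3 and 4, and 54, 30, 50 and 224 without combination library 1, 2, 3 and 4. The pericyte call by camera ended without anti-PD1 library 3 (-0.40) or vorinostat library 4 (-0.38).

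Vorinostat averaged over both backgrounds changed 2 genes, which were named after their values were seen. Lilr4b rose by 0.74 (SE 0.10, adjusted p = 0.0438), and Gm38061 fell by 1.36 (SE 0.08, adjusted p = 6.47e-06). The fall of Gm38061 comes from the background without anti-PD1 alone (-2.65, against -0.08 with it, adjusted p = 0.677). With median-of-ratios scaling 1 gene passed, lower. There were 896 genes at an unadjusted p under 0.05, against 970 by chance, and voom called 2. The count was 0 without any control library, 4 without anti-PD1 library 3, 6 without combination library 4 and 3 without combination library 3. It was 1 without anti-PD1 library 1 or 4, any vorinostat library or combination library 1 or 2. Lilr4b passed without anti-PD1 library 3 or combination library 3 or 4 and in no other fit that left out a library. It lost its call with a pseudocount of 0.1, median-of-ratios scaling, quantile normalization, voom and among protein-coding genes alone. The count was also 1 with the replicate number as a block, the neuron mean as a covariate or the 10 most abundant genes left out. With a mean of at least 5 TPM the count was 0. The histone genes H2bc11 (0.63, SE 0.12) and H4c12 (0.68, SE 0.14), Nkapl (0.71), the lipase gene Dagla (-0.36), Mgat3 (-0.23) and Tsc22d1 (-0.23) did not pass. The fixed genes had values of 0.03 for Cdkn1a, 0.18 for H1f0, 0.23 for Hdac1, 0.20 for Hdac2, 0.04 for Hdac3, 0.03 for Pdcd1 and 0.04 for Cd274. Cd8a was at 0.18, Gzmb 0.04, H2-K1 0.03, Mki67 0.07, Olig2 0.23 and Pdgfra 0.03, and those of Cdkn1a, H2-K1 and Pdgfra turn to -0.02 with median-of-ratios scaling. The mean of the deacetylase inhibitor response list was 0.07 (0 of 16 past, 1 rose adjusted over the list alone), and neurons were lower by camera (mean -0.32, adjusted p = 1.35e-05, and adjusted p = 0.981 with an estimated correlation). Without vorinostat library 3 the neuron mean was -0.14. The cell cycle mean was 0.22 (adjusted p = 0.287). Fry called 0 lists (1 unadjusted).

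Whether the combination departed from the sum of the single agents was addressed by the interaction on the log2 scale. None of the fixed immune genes passed. Gzmb was at 0.07 (SE 0.29, and -0.01 with quantile normalization), H2-K1 -0.24 (SE 0.54), Cd8a -0.05 (SE 0.43), Cd274 0.02 (SE 0.36, and -0.14 with median-of-ratios scaling) and Pdcd1 0.34 (SE 0.28). The lists were at -0.09 for MHC class I (adjusted p = 0.214) and -0.14 for T cells (adjusted p = 0.462). Of 19390 genes 2 had an interaction, and these were named after their values were seen. They are 2700046G09Rik (1.14, SE 0.15, adjusted p = 0.0348) and Gm38061 (2.58, SE 0.17, adjusted p = 1.34e-05), with 3182 at an unadjusted p under 0.05 and 1 by voom. Gm38061 had 0 or 1 reads in each library of the 3 treated groups (at most 0.233 TPM), so no further fall could be measured, and its value follows from that floor. 2700046G09Rik passed without anti-PD1 library 2 or vorinostat library 3 and in no other fit that left out 1 library. It lost its call with a pseudocount of 0.1, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, voom and the neuron mean as a covariate, and among protein-coding genes, which leave both genes out, the count was 0. The count was 0 without any control library, 3 without anti-PD1 library 2, 5 without vorinostat library 3 and 1 without any other library. It was 1 with the replicate number as a block. Not past the threshold were the signalling ligand gene Wnt5a (1.11, SE 0.17, adjusted p = 0.124), the fatty acid elongase gene Elovl2 (0.72), Tmem203 (0.79), Rap1gap (-0.82), Mir5620 (-1.01) and Mir5125 (-0.74). The same holds for Cdkn1a (0.52), H1f0 (0.90), Hdac1 (0.86), Hdac2 (0.72), Hdac3 (0.30), Mki67 (0.80), Olig2 (0.28) and Pdgfra (0.14, and -0.09 with median-of-ratios scaling). By camera neurons (mean -0.99, adjusted p = 1.51e-08), ependyma (-0.77, 0.0187), erythrocytes (-2.31, 0.0187), astrocytes (-0.34, 0.036) and microglia (-0.05, median -0.18, 0.036) were lower and the cell cycle (0.92, 0.023) higher. Each had adjusted p = 0.934 with an estimated correlation, and fry called 0 lists (1 unadjusted). Means moved to -0.15 for microglia without control library 2, -0.11 for microglia and -1.51 for erythrocytes without anti-PD1 library 1, and 1.45 for the cell cycle without combination library 2. Leaving out 1 library ended the neuron call in no case and each of the others in at least 1. Those were erythrocytes without control library 2 (-1.24) or anti-PD1 library 2 (-1.99) and ependyma without control library 1 (-0.58), anti-PD1 library 2 (-0.47) or combination library 4 (-0.54). The cell cycle call ended without anti-PD1 library 2 (0.62), control library 3 (0.83), vorinostat library 1 (0.75) or 4 (0.76) or combination library 1 (0.81), 3 (0.68) or 4 (0.75). That of astrocytes ended without control library 2 (-0.30) or 3 (-0.22), anti-PD1 library 2 (-0.30) or 4 (-0.36), vorinostat library 2 (-0.27) or 4 (-0.27) or combination library 2 (-0.36) or 4 (-0.28), and that of microglia without control library 1 (0.03) or 3 (-0.04), anti-PD1 library 2 (-0.06) or 4 (0), vorinostat library 3 (-0.05) or combination library 2 (-0.06) or 4 (-0.05).

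Across the 19390 genes, which are not independent replicates, the changes with anti-PD1 in the absence and presence of vorinostat had a Pearson correlation of 0.27 and a Spearman correlation of 0.23. These differences share no library. In the permutation 13 of 100 groupings of the libraries, the real one counted among them, gave a Pearson value as high (permutation p = 0.13, and 0.26 for Spearman). The changes with vorinostat in the absence and presence of anti-PD1 had correlations of -0.29 and -0.36 (permutation p = 0.78 and 0.8). Leaving out 1 library moved the first Pearson value between -0.06 and 0.43 and the second between -0.49 and -0.07.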

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

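Of the tests in this part, the 9 of explanations were chosen only after the results were seen, and the 13 that split the libraries in other ways were chosen before.

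With anti-PD1 alone cell cycle genes were lower than in controls (mean change -1.34, SE 0.55) and neuron genes higher, and a larger share of normal brain in the pieces could give both. With the neuron mean as a covariate the cell cycle change was -0.29 (SE 0.43), as that explanation predicts, while with median-of-ratios scaling it was -1.17 (SE 0.51), which argues against a few abundant genes taking most of the TPM. Striatal neuron genes exceeded cortical ones by 1.48 (exact p = 0.0571), in all 4 libraries by more than in any control, where a share of brain of unchanged makeup predicts about 0. The striatal list was chosen after its genes were seen to rise, so this alone does not exclude unchanged makeup, and brain from another place stays open too. The neuron mean is itself measured in the same pieces and could follow the treatment, so an effect of the antibody on division of tumour cells stays open.

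MHC class I, T cell and cytotoxic genes were higher with anti-PD1 in both backgrounds (mean of the 3 lists 0.71, SE 0.15). With the neuron mean as a covariate the value was 0.62 (SE 0.17), with median-of-ratios scaling 0.75 (SE 0.17) and with the erythrocyte mean as a covariate 0.73 (SE 0.14). For the mean of the 3 lists, these values argue against normal brain, abundant genes and blood as the only source. Single calls were less firm: with the neuron covariate 1026 genes became 22 in anti-PD1 vs control, and the T cell call ended. Over both backgrounds H2-Q7, H2-Q6 and H2-D1 lost their calls with that covariate. Gzmb and Cd8a pass the filter only by their level with anti-PD1, so the mean can overstate the rise. More T cells or more interferon signalling in the pieces could give such values. Which of these it is, and whether it is an effect of the antibody or of where the pieces were taken, was not tested.

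Vorinostat library 4 had 229 genes at 1 TPM or more that lay under 0.2 TPM in the 14 other libraries, and 155 of them are olfactory receptor genes (67.7%, against 2.5% of the table; Fisher p = 4.15e-195). Of 25 olfactory mucosa genes 16 were at 3 times the highest other library or more, as RNA of olfactory mucosa predicts. The deepest library had 11 such genes, and the most in another vorinostat library was 24, which argues against depth and against the treatment. Tissue taken along at dissection and RNA carried over later are possibly both involved, and stay open.

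Other splits of the same libraries were counted for each result. In vorinostat vs control 9 of 35 splits gave as many genes (real 1, highest other 1) and 31 as many lists (real 4, highest other 17). In anti-PD1 vs control 2 of 35 gave as many genes (real 1026, highest other 5099) and 12 as many lists (real 12, highest other 16). In combination vs control the numbers were 2 (real 4, highest other 20) and 5 (real 14, highest other 15), and in combination vs anti-PD1 7 (real 3, highest other 3758) and 34 (real 2, highest other 16). Chance is not excluded for these. In combination vs anti-PD1, where library numbers go together, 8 of the splits part all 4 pairs, as the real one does. These gave at most 1 other gene (real 3), and 0 with the number as a block (real 115), and 8 are too few for a share under 0.05. By camera all 8 gave as many lists or more (real 2, highest other 15, and 16 with the block). The splits with more genes leave at least 2 pairs whole, as any split that does not part all 4 must. In combination vs vorinostat 4 splits gave as many genes (real 2, highest other 4), and for the lists only the real split, 1 of 35, gave 17 (highest other 13). That share, 0.0286, is the smallest that 35 splits can give, it is 1 of 13 such shares and not corrected for them, and the 17 calls are lost with an estimated correlation. For the other results 100 draws were used, the real grouping counted among them. Of these, 7 gave as many interaction genes (real 2, highest other 4) and 8 as many for vorinostat averaged (real 2, highest other 13). For anti-PD1 averaged 3 gave as many (real 91, highest other 4525). The last share is under 0.05 but likewise not corrected for the 13. The split with 5099 genes set anti-PD1 libraries 1, 2 and 4 against the controls and anti-PD1 library 3. That with 20 set combination libraries 1, 2 and 3 against the controls and combination library 4. That with 3758 exchanged anti-PD1 library 3 and combination library 2. These splits keep most of the treatment contrast, but those with 5099 and 3758 genes also part the libraries along the first principal component. In the first, anti-PD1 libraries 1, 2 and 4 had values of 38, 88.6 and 33.2 there. Anti-PD1 library 3 had 3.1 and the controls -13.3, -28.6 and -41.4. In the second, combination library 2 (43.7) joined the higher side. On the lower side were anti-PD1 library 3 and combination libraries 1, 3 and 4 (-4.5, -28.8 and -34.7). Their counts so cannot tell the treatment from that component.

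Within groups of 4 the highest and lowest library were compared with the others, and 17 of 300 measures stood apart, where chance flags about 1 in 20, or 15. Combination library 2 was lowest for immune checkpoint genes (list mean 2.22), dendritic cells (2.95) and the cell cycle (3.18), and in reads (81.2 M). Vorinostat library 3 was lowest for mature oligodendrocytes (3.92), and highest in reads (126 M) and in Spp1 (259 TPM). Vorinostat library 4 was highest for erythrocytes (11.76), Igkj5 (26.4 TPM), Fam43b (32 TPM) and Gm38061 (0.203 TPM). Also apart were Gzmb in vorinostat library 2 (0.116 TPM), Gm38061 in anti-PD1 library 3 (0.233), Klk7 in anti-PD1 library 2 (0.16) and combination library 4 (0.69), and Wnt5a (8.68) and H2-Q7 (20.3) in combination library 3.

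The effect of 1 agent differed with the other present, by limma's interaction test, for 2700046G09Rik (1.14) and Gm38061 (2.58). The value of Gm38061 follows from a floor, with 0 or 1 reads in every treated library, and tells nothing of how the agents act together. By camera it differed for microglia (-0.05), neurons (-0.99), astrocytes (-0.34), ependyma and choroid plexus (-0.77), the cell cycle (0.92) and erythrocytes (-2.31). Each of these 6 lists had adjusted p = 0.934 with an estimated correlation, and fry called 0. Each of the calls but that of neurons ends without at least 1 single library, and the microglia mean is 0.03 without control library 1.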

How the results depend on the processing

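The counts depend on the processing throughout, and fewer than 5 genes in most comparisons leave little to compare. Voom on recovered reads, protein-coding genes alone, and anti-PD1 library 2 and combination library 2 left out together were chosen after seeing the data. The cause was not tested except where named. The alternative with only the groups compared gives no value for the interaction and the averaged effects.

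Counts of genes that changed were, in the reported fit, 1 for vorinostat, 1026 for anti-PD1 and 4 for the combination vs control, 3 for combination vs anti-PD1, 2 for combination vs vorinostat, 2 for the interaction, 2 for vorinostat averaged and 91 for anti-PD1 averaged. Leaving out 1 library gave ranges of 0 to 2, 0 to 4982, 2 to 13, 0 to 671, 0 to 9, 0 to 5, 0 to 6 and 7 to 565, in that order. List counts were 4, 12, 14, 2 and 17 for the first 5 and ranged over 0 to 10, 11 to 15, 11 to 16, 1 to 6 and 11 to 17. The correlation of the effects of vorinostat in both backgrounds ranged from -0.49 to -0.07 and that of anti-PD1 from -0.06 to 0.43.

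With no filter the gene counts were 4 for vorinostat vs control (1 list), 300 for anti-PD1 vs control, 8 for combination vs control, 14 for combination vs anti-PD1, 9 for the interaction, 6 for vorinostat averaged and 60 for anti-PD1 averaged. With a mean of at least 5 TPM they were 0 for vorinostat vs control, combination vs control, combination vs vorinostat, the interaction and vorinostat averaged, 11 for combination vs anti-PD1 and 53 for anti-PD1 averaged. Gm38061, Lilr4b and Klk7 lie below that filter. List counts there were 7 for vorinostat, 7 for anti-PD1 and 9 for combination vs control and 11 for combination vs vorinostat. A pseudocount of 0.1 gave 0 genes for combination vs anti-PD1 (1 list), combination vs vorinostat, the interaction and vorinostat averaged.

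Median-of-ratios scaling gave 1 gene for combination vs vorinostat, the interaction and vorinostat averaged, 210 for anti-PD1 averaged, and 1 list for vorinostat vs control. Quantile normalization gave 0 for combination vs anti-PD1, 1 for combination vs vorinostat, the interaction and vorinostat averaged, and 217 for anti-PD1 averaged. With the 10 most abundant genes left out there was 1 for combination vs anti-PD1, combination vs vorinostat, the interaction and vorinostat averaged, 202 for anti-PD1 averaged, and 2 lists for vorinostat vs control. Among protein-coding genes alone there were 0 for vorinostat vs control, the interaction and vorinostat averaged, 1 for combination vs anti-PD1, 4 for combination vs vorinostat and 35 for anti-PD1 averaged.

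With arrayWeights, which gave weights from 0.33 (anti-PD1 library 2) to 3.29 (vorinostat library 2), there were 2 for vorinostat, 7079 for anti-PD1 and 34 for combination vs control, 2855 for combination vs anti-PD1, 17 for combination vs vorinostat, 1094 for the interaction and 3213 for anti-PD1 averaged. Without the trend there was 1 for combination vs anti-PD1 and combination vs vorinostat. Voom gave 603 for anti-PD1 vs control, 1 for combination vs anti-PD1, combination vs vorinostat and the interaction, 49 for anti-PD1 averaged, and 0 lists for vorinostat vs control. With only the groups compared there were 2 for vorinostat, 397 for anti-PD1 and 1 for combination vs control and 0 for combination vs anti-PD1 (1 list) and combination vs vorinostat. At an adjusted p under 0.1 there were 4382 for anti-PD1 vs control, 59 for combination vs anti-PD1 and 812 for anti-PD1 averaged. With a log2 change of at least 1 as well there were 332, 1 and 21, and 1 for combination vs vorinostat and vorinostat averaged. Camera with an estimated correlation and fry gave 0 lists for the first 5 comparisons.

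With the replicate number as a block there were 2621 genes for anti-PD1 and 20 for combination vs control, 115 for combination vs anti-PD1, 0 for combination vs vorinostat, 1 for the interaction and vorinostat averaged, 663 for anti-PD1 averaged, and 1 list for vorinostat vs control. Libraries of the same number in different groups had a median correlation of 0.12 (-0.28 to 0.64, 21 pairs) and those of different numbers -0.02, and 10 of 15 libraries went best with their own number. The block changed the calls of Ccne1 (0.61, adjusted p = 0.031) and Phlda3 (1.02, adjusted p = 0.0428) in combination vs anti-PD1 and no other named call or list there beyond those printed in the report. With the neuron mean as a covariate there were 22 genes for anti-PD1 and 30 for combination vs control, 0 for combination vs anti-PD1, 8 for combination vs vorinostat, 1 for the interaction and vorinostat averaged, 57 for anti-PD1 averaged, and 2 lists for vorinostat vs control. Without anti-PD1 library 2 and combination library 2 there were 187 for anti-PD1 vs control, 1 for combination vs anti-PD1, 0 for combination vs vorinostat and 16 for anti-PD1 averaged, and the anti-PD1 correlation was -0.02.

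List means that turned were neurons in vorinostat vs control (-0.08 without vorinostat library 4, up to 0.53 without vorinostat library 3), and in combination vs vorinostat progenitors and glioma (0.04) and the cell cycle (0.11), without combination library 2 and with anti-PD1 library 2 left out as well. Leaving out 1 library took these to -0.53 (without vorinostat library 4) and -0.66 (without combination library 3) at the other end. The mean of microglia in the interaction turned to 0.03 with arrayWeights and without control library 1. With the neuron covariate the cell cycle turned in combination vs anti-PD1 (-0.20) and in the interaction (-0.15), astrocytes (0.01) and ependyma (0.24) in the interaction, and neurons (0, by construction) and progenitors and glioma (0.04) in anti-PD1 averaged. No gene that passed was reversed. Over all alternatives the named genes that passed in anti-PD1 vs control kept their call in 597 cases and lost it with the same direction in 417, in anti-PD1 averaged in 192 and 76, in combination vs control in 105 and 7, in combination vs anti-PD1 in 37 and 49, in combination vs vorinostat in 27 and 30, and in the interaction and vorinostat averaged in 32 and 22 each. With 81.2 M to 161.5 M reads per library, low genes rest on few reads: Gzmb has 18 to 69 in the libraries that received anti-PD1.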

Other observations

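The families and counts in this part were chosen only after the results were seen, and their p-values were adjusted over these families alone.

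Genes of striatal projection neurons, which carry the dopamine receptors of the striatum, were higher with anti-PD1 than in controls. Of 18 listed genes 17 are expressed in these pieces, and 10 rose, with a mean change of 2.05 (2.22 with median-of-ratios scaling). The list mean was 3.31 ± 0.11 in controls and 5.36 ± 0.44 with anti-PD1 (n = 3 and 4). The dopamine receptor gene Drd1 rose by 2.48 and the phosphodiesterase gene Pde10a by 1.35. Camera gave an adjusted p = 1.53e-18, camera with an estimated correlation 0.135 and fry 0.00658. The list was also higher by camera in vorinostat vs control (mean 0.88, 1.06e-18, 0.218 with an estimated correlation, fry 0.497) and combination vs control (mean 0.86, 1.12e-11, 0.213 and 0.238), with all 17 genes positive and 0 past in each, though combination library 4 lay below the controls. In combination vs anti-PD1 the striatal list was lower, with a mean of -1.19, all 17 genes negative and 0 past (camera 5.79e-14, 0.306 with an estimated correlation, fry 0.0735). All 12 cortical excitatory neuron genes listed are expressed. Their mean change in anti-PD1 vs control was 0.57 (camera 0.000584, 0.41 with an estimated correlation, fry 0.125). Of 97 expressed immunoglobulin V segments 12 rose with anti-PD1, with a mean of 1.65 (fry 0.0341, and 0.135 for camera with an estimated correlation). A segment near 0 in controls enters this list only by its level in treated libraries, so the filter favours positive changes and the mean and the test can overstate the rise. Their mean was 1.96 ± 0.80 with anti-PD1, 0.31 ± 0.28 in controls and 0.64 ± 0.17 with vorinostat. Combination libraries 1, 2 and 3 stood at 2.18, 2.14 and 1.53, and combination library 4 at 0.12. In combination vs control their mean change was 1.18, with 87 of 97 positive, 9 negative and 0 past. Fry gave an adjusted p = 0.238 there, and camera with an estimated correlation 0.213.

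Histone genes were higher with vorinostat averaged over both backgrounds in direction alone. Of 59 expressed 54 were positive and 0 passed, with a mean of 0.35 (0.32 with median-of-ratios scaling, fry adjusted p = 0.0861, and 0.226 for camera with an estimated correlation). In combination vs anti-PD1 57 of 59 were positive with a mean of 0.57 (0.45 with median-of-ratios scaling, fry 0.0319, and 0.306 for camera with an estimated correlation). All 74 ribosomal protein genes were positive there too (mean 0.41, 0.518 for camera with an estimated correlation), while in combination vs control 49 of 59 histone genes were positive (mean 0.35) and 71 of 74 ribosomal protein genes negative (mean -0.11). Histone genes are near-identical copies, so single values are uncertain. Of 74 ribosomal protein genes 72 were negative in anti-PD1 vs control and 1 fell, with a mean of -0.52 (-0.33 with median-of-ratios scaling, 0.595 for camera with an estimated correlation). The mean of 85 respiratory chain genes was -0.07 there and turned to 0.11 with that scaling.

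Single libraries held genes of other tissues. In vorinostat library 4 the olfactory neuron gene Omp stood at 91.9 TPM (highest other 8.56), Cyp2f2 at 57.3 (0.284) and Scgb1c1 at 47.8 (2.66). In anti-PD1 library 2 10 of 18 skeletal muscle genes were at 3 times the highest other library or more, among them Myoz1 (17.3 TPM against 0.237) and Acta1 (66.3 against 19.8). Control library 1 held 129 reads of the retinal and sensory neuron gene Pou4f2 and 21 of Evx2. Gm38061 had 22, 24 and 40 reads in the controls and at most 1 in any other library. Klk7 had 94, 75, 89 and 44 reads in the combination libraries, 10 in anti-PD1 library 2 and 0 elsewhere.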
